A study of Mus musculus with 12 samples.

How the data were processed

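Live CD45+ cells were sorted from transplanted mouse tumours, named MCA38 sarcoma in the design text of the series, while the titles name the model otherwise, with MC38 in brackets. Droplet libraries were made with the Chromium 3' chemistry and sequenced on a NovaSeq, per the labels. The 12 libraries fall into 6 groups of 2. The genotype experiment holds TREM2_KO and TREM2_WT. The antibody experiment holds CTRL, aPD1, aTREM2 and aTREM2-aPD1, with antibodies against PD-1, TREM2 or both. The labels do not say whether the 2 libraries of a group came from separate mice, so every p-value below measures the spread between these libraries, which may be technical.

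The deposited matrices hold raw UMI counts per gene and cell barcode. Cell Ranger, Seurat and the mm10 build are named in the submitters' processing notes. Their versions, the aligner settings and the filters on cells are not given in the sources used here. The authors also deposited annotation tables, per the file headers, with the library name, the total UMI count and a cluster number of each cell they kept. The cluster number is an arbitrary code, listed by the authors as a score without order. All CD45+ cells, the macrophages and, in the genotype experiment, the lymphoid cells have such tables. The deposited matrices hold 67070 barcodes, of which the annotation keeps 41567. The annotated UMI total equals the matrix total for every cell.

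The titles name 4 libraries otherwise than the annotation and the names of the deposited matrices do. The libraries titled aTREM2 are named as the combination of both antibodies in both of these sources, and those titled aTREM2-aPD1 are named there as the TREM2 antibody alone. Groups follow the titles throughout, and the gene tests of every comparison that separates these libraries were repeated with the labels exchanged, which was not done for the tests of lists and shares. The comparison of all 4 libraries with the TREM2 antibody against the 4 without it is the same under either naming.

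Annotated cells entered without a further filter. The planned minimum of 2000 UMIs per cell would remove 3 cells. No doublet caller was run here, and whether the authors removed doublets is not given in the sources used here. T-cell-like and NK-like droplets whose share of macrophage marker UMIs exceeded 0.1 times the median share in the macrophages of their library were left out in an added alternative. Macrophages are the cells of the deposited macrophage tables. The other classes are clusters of the CD45+ tables, named from 17 marker lists. A cluster whose leading genes pointed to more than a single type stayed unnamed. T/NK cells are the T-cell-like and NK-like clusters together. In the antibody experiment they include a cluster led by Tcrg-C1, Trdc and Il17a and a cluster led by Klra and Cd3 genes. Where several gene IDs share a symbol, the ID with most UMIs kept it and the others stayed as separate rows. The matrices hold 31053 gene rows. Gene positions are those of the GENCODE annotation on mm10.

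UMI counts were summed per library over the macrophages and over the T/NK cells. These sums were tested with the quasi-likelihood test of edgeR 4.0.16 with a robust fit, TMM scaling and the filterByExpr filter, and p-values were adjusted with the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05. CPM values beside a fold change are group means of TMM-scaled CPM, and CPM values of a single library divide a gene's UMIs by all UMIs of its class. Residual degrees of freedom are 2 in the genotype experiment and 4 in the antibody experiment. Standard errors were derived from the fold change and the F statistic. Each named comparison in the antibody experiment comes from 1 fit of 8 libraries. The interaction is the effect of the TREM2 antibody with the PD-1 antibody minus its effect without it. Numbers of cells per class or macrophage cluster were tested with edgeR as well, with the library's cells as offset. All these tests are two-sided, as are the exact permutation tests of shares, which cannot go below p = 0.33 with 2 libraries against 2.

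Before the data were examined, 20 gene lists, the markers, the tests, the alternatives and the rule for named genes were fixed. The rule takes Trem2, the called genes with the largest rises and falls (up to 8 each way in the 4 leading comparisons and 5 each way in the others) among genes with a mean of at least 20 CPM and no overlap between sides, and up to 3 called members per list. Gene models without a symbol of their own and antigen receptor segments were left out, where no member of a list was called the member with the smallest p is given as a value, and a comparison with 5 or fewer calls names all of them. The myeloid lists are the lipid-associated TREM2 program, complement, alternative activation of the CD206 type, mature macrophage, monocyte, iNOS and inflammatory cytokine, costimulation and activation, and extracellular matrix remodelling. The lymphoid lists are cytotoxic effector, T cell exhaustion and checkpoint, naive and memory T cell, and regulatory T cell. The shared lists are type I interferon response, interferon gamma response, MHC class I, MHC class II, hypoxia and glycolysis, proliferation, dissociation stress and mitochondrial transcripts. Lists with at least 3 measured members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry.

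Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, a replicate block, each library left out in turn, other definitions of the classes, exchanged labels and a minimum of 50 CPM in place of 20 for the comparison of fold changes. Cells of 5000 to 40000 UMIs, NK-like or T-cell-like cells alone, and T/NK cells without droplets rich in macrophage markers were added after the data were seen. Where a group keeps a single library, that library is assumed to vary like the other groups.

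The tests were tried on simulated data with 200 changed genes drawn from the means of the real libraries. Each gene was drawn independently, so shifts between replicate libraries that many genes share are absent. The rates below therefore need not hold for the real libraries. In macrophages of the genotype comparison, over 13623 genes, 28.4% of genes changed 1.5-fold, 53.7% changed 2-fold and 87.9% changed 4-fold were recovered, and 39 of 152 calls were false. In macrophages of the TREM2 antibody comparison, over 12589 genes, 64.2%, 79.1% and 97.0% were recovered at these sizes, with 23 of 183 calls false. In T/NK cells of the genotype comparison, over 10031 genes, the shares were 38.8%, 73.1% and 95.5%, with 18 of 156 calls false. In T/NK cells of the TREM2 antibody comparison, over 10701 genes, the shares were 55.2%, 85.1% and 98.5%, with 17 of 176 calls false. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.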

Results

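The series asked how the loss of TREM2, a lipid-sensing receptor of myeloid cells, or an antibody against it, with or without a PD-1 antibody, changes the immune cells of a mouse tumour. PD-1 is an inhibitory receptor of T cells, and its blockade is used as cancer immunotherapy. Single-cell RNA was measured in sorted live CD45+ cells of transplanted tumours, named MCA38 sarcoma in the design text of the series while the titles name the model otherwise, with MC38 in brackets, in 12 libraries of 6 groups with 2 libraries each. The genotype experiment compared TREM2_KO with TREM2_WT, and its annotation holds 19758 cells, of which 15739 are macrophages and 1746 are T/NK cells. The antibody experiment holds CTRL, aPD1, aTREM2 and aTREM2-aPD1, with 21809 annotated cells, 14111 macrophages and 4552 T/NK cells.

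Annotated cells per library numbered 2246 and 2269 in aPD1, 2112 and 3118 in aTREM2, 3014 and 2526 in aTREM2-aPD1, 3413 and 3111 in CTRL, 5727 and 4050 in TREM2_KO, and 4864 and 5117 in TREM2_WT. Their UMIs totalled 31431060 and 35880570 in aPD1, 28533899 and 42335720 in aTREM2, 44459858 and 43662059 in aTREM2-aPD1, and 41803193 and 49143291 in CTRL. TREM2_KO held 75289689 and 60122220 UMIs and TREM2_WT 96902721 and 91637633. Macrophages carried between 17685433 UMIs (aPD1 1) and 78653142 UMIs (TREM2_WT 2). T/NK cells carried between 2179697 UMIs (TREM2_WT 2) and 10699218 UMIs (CTRL 1). Median UMIs per cell lay between 10396 (CTRL 1) and 16360 (TREM2_WT 1), and mitochondrial transcripts made up 3.22% to 4.76% of UMIs. Both libraries of every group differed by more than counting noise, with a chi-square per degree of freedom from 3.69 in TREM2_KO to 146 in TREM2_WT.

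The libraries titled aTREM2 carry the name of the combination both in the deposited annotation and in the names of their deposited matrices, and those titled aTREM2-aPD1 carry in both the name of the TREM2 antibody alone. Below, group names follow the titles, and the reading under the annotation's names is given for the gene counts and for the shares of cells. Tests of lists and shares were not repeated under it.

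Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, mm10) fell in the macrophages of the knockout libraries. The gene stood at 21.2 and 20.7 CPM in the macrophages of TREM2_KO and at 381 and 283 CPM in those of TREM2_WT. The log2 fold change was −3.99 ± 0.15 (SE, n = 2 libraries per group, edgeR adjusted p = 0.024). In the antibody experiment, where the gene is intact, Trem2 lay between 316 and 368 CPM in macrophages of all 8 libraries, and its log2 fold change with the TREM2 antibody was 0.02 ± 0.08 (SE, n = 4 per side, edgeR adjusted p = 0.86). The labels do not say which part of the gene was deleted. A 3' tag outside the deleted part would check nothing, so the 1233 and 941 Trem2 UMIs that remained in TREM2_KO macrophages cannot be placed in the gene. Without either TREM2_KO library the call was lost, at −4.00 without TREM2_KO 1 and −3.96 without TREM2_KO 2.

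**Figure D1:**
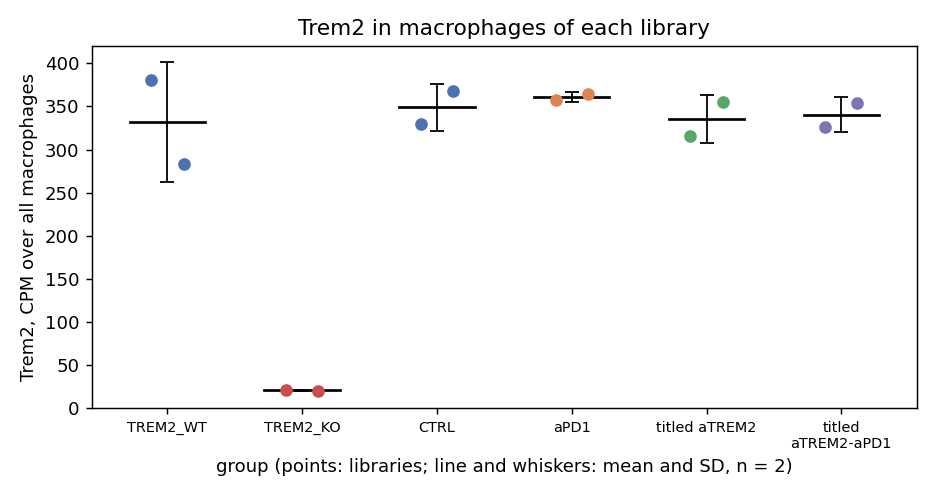
Trem2 in macrophages of each library, in CPM (vertical axis), by group (horizontal axis), with points for libraries and a line with whiskers for the mean and SD of n = 2. TREM2_KO sits at 21.2 and 20.7 CPM, and the other 10 libraries lie between 283 and 381 CPM.

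The comparison of TREM2_KO with TREM2_WT macrophages asked what the receptor's loss changes in the cells that carry it. Besides Trem2, 3 genes fell. Dmkn, which encodes the secreted protein dermokine, went from 10.2 to 1.31 CPM (−2.96 ± 0.11). Nt5e, the ectonucleotidase CD73 that makes adenosine from AMP, went from 23.5 to 5.19 CPM (−2.18 ± 0.09). Gm47283, a gene model that the annotation places on chromosome Y, went from 53.9 to 17.1 CPM (−1.65 ± 0.07; log2 fold changes with SE, n = 2 per group, edgeR adjusted p = 0.024 for each). Gm47283 stood between 92.8 and 140 CPM in macrophages of the antibody libraries, in which the chromosome Y gene Ddx3y had 0 UMIs. The fall of Gm47283 was not limited to macrophages. In NK-like cells it averaged 29.2 CPM in TREM2_KO and 88.0 CPM in TREM2_WT, where Trem2 averaged 1.12 and 8.26 CPM. Gm42418, a transcript that overlaps ribosomal RNA and was chosen after its values were seen, stood at 26027 and 25664 CPM in TREM2_KO and 16940 and 20065 CPM in TREM2_WT (0.47 ± 0.14, edgeR adjusted p = 0.124).

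Several well-known macrophage genes did not pass the test. Spp1, which encodes the secreted matrix protein osteopontin, stood at 49.8 CPM in TREM2_KO and 231 CPM in TREM2_WT (log2 −2.22 ± 0.13, edgeR adjusted p = 0.0597). Lyve1, a hyaluronan receptor of tissue-resident macrophages, stood at −3.12 ± 0.22, fibronectin (Fn1) at −1.18 ± 0.11, and the monocyte chemokine gene Ccl7 at −1.18 ± 0.09. On the other side were Cxcl9, an interferon-inducible chemokine that attracts T cells, at 1.02 ± 0.15, the activation marker Cd83 at 0.84 ± 0.07, the early response gene Egr1 at 0.78 ± 0.09, Ciita, the master regulator of MHC class II, at 0.53 ± 0.14 and Mertk, a receptor for dying cells, at 0.41 ± 0.08. The glycolytic gene Eno1 stood at −0.64 ± 0.08, Mcm6, a part of the replicative helicase, at −0.67 ± 0.14, Ifit3, an interferon-induced gene, at −0.69 ± 0.15, C5ar1 at −0.35 ± 0.09, B2m at 0.47 ± 0.24 and mt-Co1 at 0.20 ± 0.08, with edgeR adjusted p between 0.0597 (Lyve1) and 0.257 (B2m).

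No member of a gene list passed over all genes in these macrophages, and the lists were read as sets. Genes of alternative activation of the CD206 type lay lower in TREM2_KO, with a median log2 fold change of −0.76 over 20 measured members (camera adjusted p = 0.00593, adjusted p = 0.783 with an estimated correlation). Adjusted over the list alone, 5 of them fell and 1 rose. The proliferation list lay lower (median −0.75 over 15 members, camera adjusted p = 4.6e-05), as did the type I interferon response (median −0.34 over 15 members, camera adjusted p = 0.0168). MHC class II lay higher, with 7 of 8 members positive and a median of 0.49 (camera adjusted p = 0.0405). Each of these calls was lost with an estimated correlation, at an adjusted p = 0.783. The lipid-associated TREM2 program showed no direction, with 11 of 22 members positive and a median of −0.01 (camera adjusted p = 0.97). Markers of other cell types moved with these lists. T cell markers lay higher in TREM2_KO (median 0.87, camera adjusted p = 0.00274, adjusted p = 0.892 with an estimated correlation), as did the lists of cytotoxic effector and exhaustion genes (camera adjusted p = 0.00773 and 0.0125, adjusted p = 0.783 with an estimated correlation). Mast cell or basophil markers had a median of 1.97 (camera adjusted p = 1.4e-05, adjusted p = 0.595 with an estimated correlation).

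Of 13623 genes tested in macrophages by edgeR, 3964 had an unadjusted p below the threshold of 0.05 and 4 passed after adjustment. DESeq2 called 1386, and edgeR with a replicate block called 0. The groups of 2 did not overlap in 72.2% of genes above 20 CPM, where chance gives 33.3%. The count was 0 without TREM2_KO 1, 0 without TREM2_KO 2, 5771 without TREM2_WT 1 and 7550 without TREM2_WT 2.

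The deposited macrophage clusters shifted between the genotypes. Cluster 0, led by hemoglobin genes, Dnase1l3, Dusp2, Cxcr4 and Ccrl2, made up 53.3% ± 1.78 of the macrophages in TREM2_KO and 10.1% ± 5.14 in TREM2_WT (SD, n = 2; log2 2.40 ± 0.46, edgeR adjusted p = 0.0312). Leading genes come from sums over all libraries of the experiment. Hemoglobin transcripts made up 0.00585% of UMIs over all cells of TREM2_KO 1 and 1.83e-05% in TREM2_KO 2. The hemoglobin lead thus need not describe the cluster in both libraries. Cluster 3, led by Chil3 and the interferon-induced genes Ifit1, Ifit3 and Mx1, made up 5.11% ± 0.307 against 19.2% ± 3.15 (log2 −1.91 ± 0.24, edgeR adjusted p = 0.0152). Cluster 4, led by the alternative-activation gene Retnla with Lpl and Clec10a, made up 5.61% ± 0.537 against 10.8% ± 0.258 (edgeR adjusted p = 0.0344). The cycling cluster 6, led by Top2a, Birc5 and Mki67, made up 3.53% ± 0.171 against 7.72% ± 2.81 (edgeR adjusted p = 0.0456), and cluster 7, led by Ace and Adgre4, 0.507% ± 0.123 against 1.07% ± 0.152 (edgeR adjusted p = 0.0421). Cluster 5, led by Fcrls, Gas6 and Folr2, made up 0.457% and 0.484% in TREM2_KO, and 23.5% and 2.66% in TREM2_WT. Of its 10 leading genes, 1 also passed in the other clusters. For cluster 1, led by the mast cell or basophil genes Mcpt4, Cpa3 and Cma1, and cluster 2, led by Nos2 and Arg1, the shares were 18% against 24.1% and 13.5% against 14%. Cluster 2 made up 8.60% and 19.5% in the TREM2_WT libraries, and its log2 fold change was 0.66 without TREM2_WT 2. Fewer clusters passed with a replicate block. Between 3 and 6 of the 10 leading genes of each cluster had an unadjusted p below 0.05 between the genotypes in the other clusters, where 7 to 10 were tested, and at most 1 passed after adjustment by edgeR. No cluster passed without TREM2_KO 1 (0 calls) or TREM2_KO 2 (0 calls), and all 8 passed without either TREM2_WT library.

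**Figure D2:**
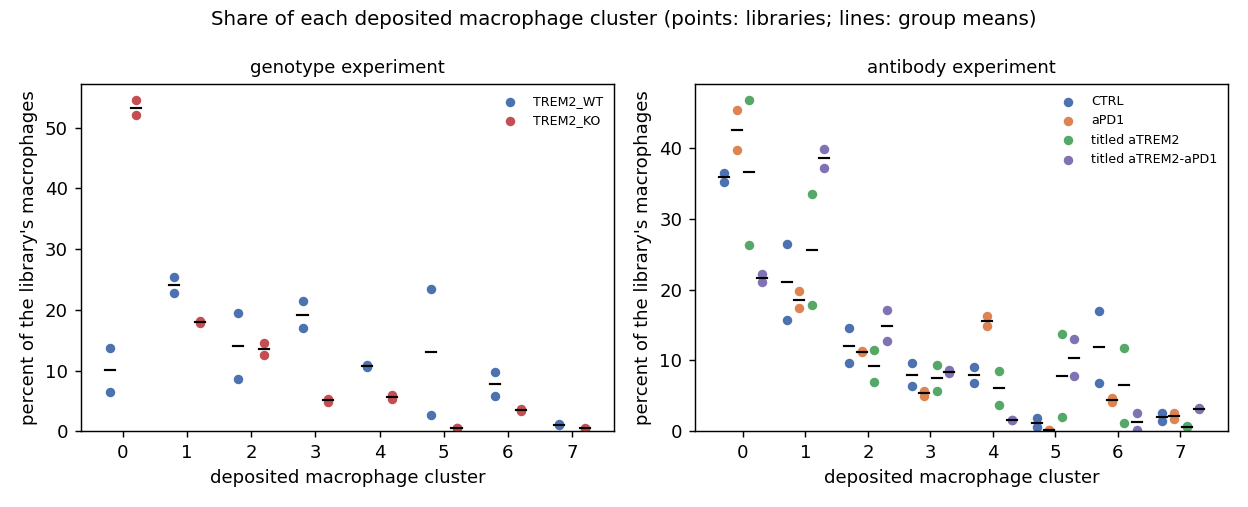
Share of each deposited macrophage cluster (horizontal axis), as a percent of the macrophages of a library (vertical axis), with points for libraries and lines for group means, in the genotype and antibody experiments. Genotype cluster 0 averages 53.3% in TREM2_KO and 10.1% in TREM2_WT, and antibody cluster 5 averages 9.11% with the TREM2 antibody and 0.688% without it.

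Lymphocytes made up more of the CD45+ cells in TREM2_KO, short of the test's threshold. NK-like cells stood at 8.18% ± 0.552 in TREM2_KO and 3.39% ± 0.617 in TREM2_WT (SD, n = 2; log2 1.27 ± 0.26, edgeR adjusted p = 0.0503). T-cell-like cells stood at 4.55% ± 0.993 and 1.60% ± 0.383 (log2 1.51 ± 0.33, edgeR adjusted p = 0.0503). Macrophages stood at 76.5% ± 0.0767 and 82.7% ± 3.47, and conventional dendritic-like cells at 3.86% and 6.44% (edgeR adjusted p = 0.733 and 0.169). Neutrophil-like cells stood at 2.33% and 1.82%, an unnamed cluster with plasmacytoid dendritic and B cell genes at 1.15% and 0.324%, and fibroblast- or sarcoma-like cells at 0.578% and 1.11%. No class passed by edgeR, 3 had an unadjusted p below 0.05, and the exact permutation test cannot go below p = 0.33 here. Without TREM2_WT 1 the count was 3 and without TREM2_WT 2 it was 4.

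T/NK cells of TREM2_KO differed from those of TREM2_WT in genes known from myeloid cells and in single T cell and glycolytic genes. H2-Aa, an MHC class II chain of antigen-presenting cells, rose from 125 to 342 CPM (1.46 ± 0.19, edgeR adjusted p = 0.0285). Cxcl2, Fcgr4, Cxcl16 and Ly86, all known from myeloid cells, rose by 1.57 ± 0.20, 1.5 ± 0.25, 1.44 ± 0.18 and 1.24 ± 0.20. The T cell surface genes Cd6 and Cd4 rose by 1.30 ± 0.22 and 1.26 ± 0.24. Eno1, which encodes the glycolytic enzyme enolase, fell by 0.71 ± 0.08 (401 to 244 CPM, edgeR adjusted p = 0.000193), the chemokine gene Cxcl10 fell by 0.79 ± 0.15, and Eif2s3y, a gene on chromosome Y, fell by 1.0 ± 0.14 (log2 fold changes with SE, n = 2 per group).

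The remaining leading falls were in Agpat5, which encodes an enzyme of phospholipid synthesis (−0.95 ± 0.18), the sulfotransferase gene Sult2b1 (−0.86 ± 0.18), Cdyl (−0.78 ± 0.20), the galactokinase gene Galk1 (−0.76 ± 0.18) and P2ry14, a receptor for nucleotide sugars (−0.73 ± 0.16), with edgeR adjusted p between 0.0155 (Agpat5) and 0.0464 (Cdyl). P2ry14 stood at 0.49 in T-cell-like cells alone. Trem2 stood at 1.37 CPM in TREM2_KO and 8.57 CPM in TREM2_WT (−2.55 ± 0.90, edgeR adjusted p = 0.311).

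Among the lists read in T/NK cells, MHC class II moved most, with 3 of 7 members risen over all genes, 7 when adjusted over the list alone, and a median log2 of 1.15 (camera adjusted p = 1.4e-24, adjusted p = 0.269 with an estimated correlation). H2-DMb1 and H2-DMa, which load peptides on class II molecules, rose by 0.88 ± 0.18 and 0.55 ± 0.13, although H2-DMb1 stood at −0.11 in NK-like cells alone. The inflammatory cytokine list (median 0.96), the complement list (0.82) and the mature macrophage list (0.72) lay higher as well (camera adjusted p = 7.3e-13, 1.1e-11 and 1.3e-07, adjusted p = 0.269 with an estimated correlation). Macrophage markers moved with them, with 4 of 10 members risen, 8 when adjusted over the list alone, and a median of 0.76 (camera adjusted p = 6.9e-13, adjusted p = 0.319 with an estimated correlation). T/NK droplets rich in macrophage markers made up 9.10% and 8.55% of the T/NK cells in TREM2_KO and 4.33% and 5.94% in TREM2_WT.

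Of 16 hypoxia and glycolysis genes 5 fell and none rose, 6 fell and 1 rose when adjusted over the list alone, and the median was −0.32 (camera adjusted p = 5.4e-06, adjusted p = 0.42 with an estimated correlation). The glycolytic genes Pgk1 and Tpi1 fell by 0.53 ± 0.10 and 0.47 ± 0.09. In the dissociation stress list 5 of 14 members rose, 5 when adjusted over the list alone, led by the early response genes Fos (0.81 ± 0.09, edgeR adjusted p = 6.2e-05), Atf3 (0.79 ± 0.18) and Fosb (0.54 ± 0.09). That list had a camera adjusted p = 2e-08, lost at an adjusted p = 0.269 with an estimated correlation, and Atf3 stood at −0.30 in NK-like cells alone. Ikzf2, which encodes the transcription factor Helios of regulatory T cells, and the inhibitory receptor gene Klrg1 rose by 0.66 ± 0.09 and 0.88 ± 0.14, whereas Capg of the same regulatory T cell list fell by 0.41 ± 0.10 (camera adjusted p = 0.00265, adjusted p = 0.483 with an estimated correlation). Cd200, a ligand of an inhibitory receptor, was the member of the exhaustion list that rose (2.41 ± 0.45, 1.76 to 9.2 CPM, edgeR adjusted p = 0.00901). In the interferon gamma list, which had no camera call, Iigp1, a GTPase that acts on intracellular pathogens, rose by 0.85 ± 0.16, and Socs1, a feedback inhibitor of cytokine signals, fell by 0.62 ± 0.10. Members given as values were Bst2 (−0.30), Nlrc5 (0.41), Rrm2 (1.19), Fasl (−0.25), Bach2 (−0.23) and mt-Co1 (0.16), with edgeR adjusted p between 0.0633 (Nlrc5) and 0.547 (Bach2).

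In all, 103 genes rose and 87 fell among 10031 tested by edgeR in T/NK cells, and 49.1% of genes above 20 CPM did not overlap, where chance gives 33.3%. The count was 92 without TREM2_KO 1, 287 without TREM2_WT 1 and 736 without TREM2_WT 2, and it was 104 without the droplets rich in macrophage markers, of which 99 were among the 190. NK-like cells alone gave 193 calls and T-cell-like cells alone 38.

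The antibody experiment asked what the TREM2 antibody changes, alone and with PD-1 blockade. All 4 libraries with the TREM2 antibody against the 4 without it form the comparison that both namings leave unchanged. In macrophages, 8 genes rose and 9 fell. Hspa1a, which encodes the stress-induced chaperone HSP70, rose from 437 to 662 CPM (0.85 ± 0.11), and Dpep2, a membrane dipeptidase, rose from 73.8 to 111 CPM (0.59 ± 0.08). Fchsd2, a regulator of membrane traffic and actin, fell by 0.63 ± 0.08 (32.6 to 20.9 CPM), and Pald1, Uhmk1, which encodes a kinase, and Nabp1, which encodes a single-stranded DNA binding protein, fell by 0.50 ± 0.06, 0.53 ± 0.07 and 0.49 ± 0.07 (SE, n = 4 per side, edgeR adjusted p between 0.0364 and 0.0389). AY036118, a noncoding transcript, rose by 0.61 ± 0.07 (edgeR adjusted p = 0.0364). Gm42418 stood at −0.51 ± 0.12 (edgeR adjusted p = 0.0837). Hspa1a did not separate the sides, with 353 to 974 CPM in libraries with the antibody and 131 to 776 CPM in those without it. Its fold change averages the log2 effects without and with PD-1 blockade, so it need not equal the ratio of these means. Under the titles the gene was higher with the TREM2 antibody without PD-1 blockade and lower with it (interaction −3.58).

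Members of several fixed lists lay higher without passing. Among these were F13a1, which encodes a clotting factor of monocytes and macrophages (0.93 ± 0.18), the chemokine gene Ccl4 (0.63 ± 0.14), the Fc receptor gene Fcgr1 (0.49 ± 0.10), Isg15 (0.49 ± 0.11) and Cxcl10 (0.48 ± 0.13), both interferon-induced, the costimulatory ligand Tnfsf9 (0.41 ± 0.07), Eno1 (0.40 ± 0.12) and C5ar1 (0.54 ± 0.16). Abca1, the cholesterol exporter, stood at −0.62 ± 0.11 and Tapbp, a part of MHC class I loading, at −0.39 ± 0.11, with edgeR adjusted p between 0.0685 (Abca1) and 0.109 (Eno1) over these 10 genes. Gngt2 (0.24), H2-DMb1 (0.19), Tyms (0.38), Plaur (0.28) and mt-Co1 (−0.20) had edgeR adjusted p between 0.089 and 0.208.

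The inflammatory cytokine list lay higher with the TREM2 antibody, with 14 of 19 members positive and a median of 0.33 (camera adjusted p = 0.00133, adjusted p = 0.821 with an estimated correlation), and 3 rose when adjusted over the list alone. The type I interferon response lay higher in 14 of 15 members (median 0.22, camera adjusted p = 0.000307, adjusted p = 0.713 with an estimated correlation), with 3 risen when adjusted over the list alone. Hypoxia and glycolysis (camera adjusted p = 0.0201) and dissociation stress (0.000223) also lay higher, at an adjusted p = 0.87 and 0.541 with an estimated correlation. Costimulation, complement, interferon gamma and both MHC lists had no camera call, and the lipid-associated TREM2 program had a median of −0.02 over 22 members (camera adjusted p = 0.93). Transcripts of other cells moved with the antibody too. NK cell markers lay lower in macrophages (median −0.96, camera adjusted p = 1.6e-07), cytotoxic effector genes lay lower (median −0.69, camera adjusted p = 0.00104), and fibroblast or sarcoma markers lay higher (median 0.72, camera adjusted p = 0.00427). With an estimated correlation the adjusted p was 0.349 for the markers and 0.541 for the cytotoxic genes.

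Of 12589 genes tested by edgeR, 18.8% of those above 20 CPM did not overlap between the sides of 4, where chance gives 2.86%. The count of 17 was 0 without aPD1 1 and 0 without aPD1 2, 549 without aTREM2 1, 3 without aTREM2 2, 1 without aTREM2-aPD1 1, 424 without aTREM2-aPD1 2 and 50 without CTRL 1.

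Macrophage cluster 5, led by Cxcl3, Gpnmb, Adm, Egln3, Spp1 and Hmox1, rose to 9.11% ± 5.41 of macrophages with the TREM2 antibody from 0.688% ± 0.804 without it (SD, n = 4 per side; log2 4.37 ± 0.76, edgeR adjusted p = 0.00396). Its exact permutation p was 0.0286, adjusted to 0.229. Each library with the TREM2 antibody, from 2.01% (aTREM2 1) to 13.7% (aTREM2 2), lay above each library without it, from 0.138% (aPD1 2) to 1.85% (CTRL 2). Cluster 4, led by Ccl8, Pf4, Mrc1 and Vcam1, fell to 3.88% ± 3.26 from 11.7% ± 4.55 (log2 −1.81 ± 0.34, edgeR adjusted p = 0.00396, exact permutation p = 0.0571). Cluster 1 stood at 32.1% with the antibody and 19.8% without (edgeR adjusted p = 0.194). Without aTREM2 1, 4 clusters passed.

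Among the CD45+ cells, neutrophil-like cells rose to 3.16% ± 0.691 with the TREM2 antibody from 1.54% ± 0.374 without it (SD, n = 4 per side; log2 1.01 ± 0.24, edgeR adjusted p = 0.0382). NK-like cells stood at 9.47% ± 4.34 with it and 22.8% ± 4.36 without (log2 −1.28 ± 0.36, edgeR adjusted p = 0.0541), and macrophages at 73.3% ± 5.87 and 56.4% ± 6.21 (edgeR adjusted p = 0.143). The exact permutation p was 0.0286 for each of these 3 classes, the smallest that 4 against 4 can give, and 0.0786 after adjustment. CCR7 dendritic-like cells stood at 1.61% and 2.57%, conventional dendritic-like cells at 2.45% and 3.41%, T-cell-like cells at 3.57% and 5.48%, and unnamed proliferating cells at 1.53% and 2.58% (edgeR adjusted p between 0.0605 and 0.143). The neutrophil-like class was named from markers. Its Trem2 stood between 183 and 334 CPM in the antibody libraries, against 316 to 368 CPM in macrophages and 5.57 to 17.3 CPM in NK-like cells. Whether the class holds macrophage-like cells or mixed droplets was not tested. The neutrophil call was lost without aPD1 1, aPD1 2, aTREM2-aPD1 1, aTREM2-aPD1 2 or CTRL 1, each of which leaves 0 calls, and 5 classes passed without aTREM2 1 and 2 without aTREM2 2.

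**Figure D3:**
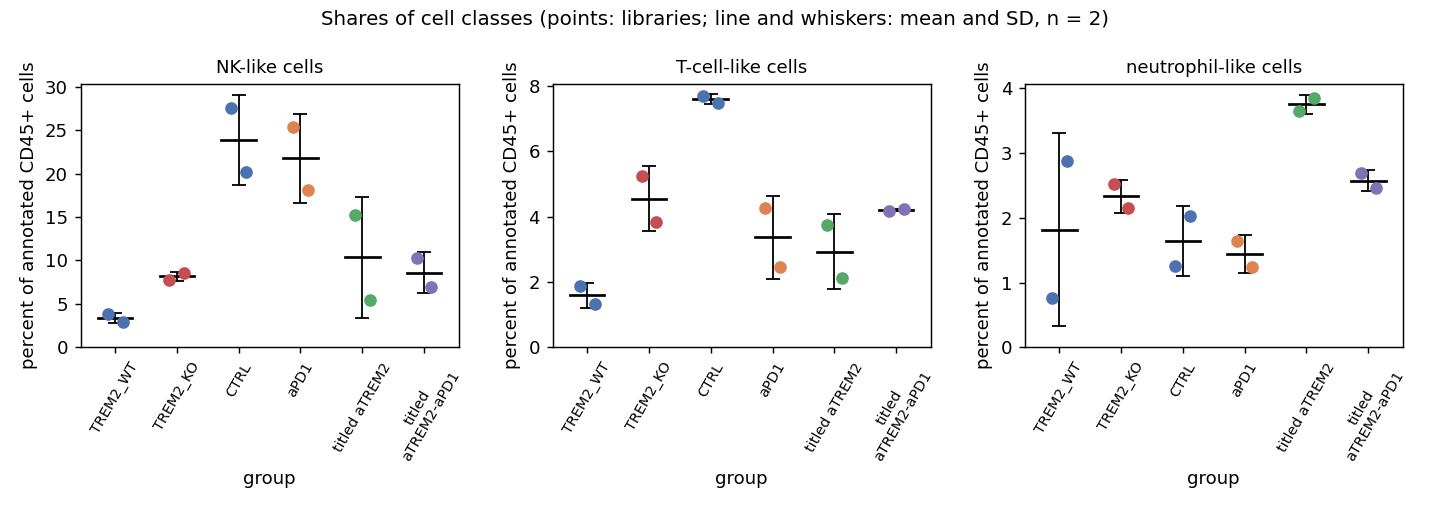
Shares of T-cell-like, NK-like and other classes, as a percent of annotated CD45+ cells (vertical axis), by group (horizontal axis), with points for libraries and a line with whiskers for the mean and SD of n = 2. NK-like cells average 8.18% in TREM2_KO and 3.39% in TREM2_WT, and 9.47% with and 22.8% without the TREM2 antibody.

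T/NK cells with the TREM2 antibody carried more T cell receptor complex transcripts. Cd3g rose from 226 to 422 CPM (0.95 ± 0.10, edgeR adjusted p = 0.00121) and Cd3e from 83.4 to 141 CPM (0.81 ± 0.14, edgeR adjusted p = 0.0439). Klf2, a transcription factor of quiescent T cells, rose from 200 to 381 CPM (0.93 ± 0.09, edgeR adjusted p = 0.000429). Nfkbia, the inhibitor of NF-kB, rose by 0.60 ± 0.07, S100a4 by 0.68 ± 0.10, Cited2 by 0.60 ± 0.10, Uhrf2 by 0.63 ± 0.09, and Cd68, a macrophage gene, by 0.86 ± 0.13 (SE, n = 4 per side). Lars2, the mitochondrial leucyl-tRNA synthetase, fell by 0.66 ± 0.08, and the integrin genes Itgb3 and Itga1 fell by 0.65 ± 0.10 and 0.51 ± 0.08. Uhmk1, Trim56, Tmem2, Rps6ka3 and Mllt6 fell by 0.48 (Mllt6) to 0.63 (Uhmk1), with edgeR adjusted p between 0.00987 (Uhmk1) and 0.0418 (Mllt6).

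T cell markers rose together in these sums, with 4 of 10 members risen, 7 when adjusted over the list alone (camera adjusted p = 1.4e-14, adjusted p = 0.134 with an estimated correlation). T-cell-like cells made up between 19.7% (aTREM2 1) and 37.9% (aTREM2-aPD1 2) of the T/NK cells with the TREM2 antibody, and between 12% (aPD1 2) and 27.0% (CTRL 2) without it. Cd3e and Ikzf2 stood at −0.25 and −0.39 in NK-like cells alone. All 9 regulatory T cell genes were positive, with Ikzf2 risen (0.51 ± 0.08) and 9 risen when adjusted over the list alone (camera adjusted p = 9.6e-10, adjusted p = 0.285 with an estimated correlation). Among 15 proliferation genes, Ube2c, which drives exit from mitosis, and Stmn1, a regulator of microtubules, rose (0.74 ± 0.17 and 0.72 ± 0.11), 5 rose when adjusted over the list alone, and the median was 0.35 (camera adjusted p = 3.4e-05, adjusted p = 0.179 with an estimated correlation). Of 14 dissociation stress genes, Jun (0.48 ± 0.09), Jund (0.47 ± 0.07) and the chaperone gene Hsp90aa1 (0.42 ± 0.09) rose, and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 9.6e-10, adjusted p = 0.285 with an estimated correlation). Igtp, an interferon-induced GTPase, rose by 0.58 ± 0.09, and Satb1, a chromatin organiser of naive T cells, fell by 0.45 ± 0.09. Macrophage markers lay higher as well (median 0.69, camera adjusted p = 1.1e-06, adjusted p = 0.332 with an estimated correlation). Of the 20 gene lists, camera at the preset correlation called 9, and 3 without T/NK droplets rich in macrophage markers. Trem2 (0.35), Xcl1 (0.22), Bhlhe40 (−0.36), Psmb8 (0.26), Bst2 (0.33), Egln3 (0.91), H2-DMa (0.41) and mt-Co1 (−0.12) did not pass, with edgeR adjusted p between 0.0632 (Bhlhe40) and 0.409 (Trem2).

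Of 10701 genes tested by edgeR 75 rose and 34 fell, and 12% of genes above 20 CPM did not overlap, where chance gives 2.86%. The count was 45 without aPD1 1, 42 without aPD1 2, 394 without aTREM2 1, 56 without aTREM2 2, 64 without aTREM2-aPD1 1, 19 without aTREM2-aPD1 2 and 1047 without CTRL 2. NK-like cells alone gave 15 calls, of which 10 were among the 109. T-cell-like cells alone gave 93 (61 risen and 32 fallen), of which 42 were. A fit of 2 groups of 4 libraries gave 23, of which 22 were among the 109.

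The single arms were set against CTRL to separate the antibodies. In macrophages of the libraries titled aTREM2, which the annotation names the combination, 15 genes rose and none fell against CTRL, where 2164 genes had an unadjusted p below 0.05. Hspa1a rose from 152 to 948 CPM (2.65 ± 0.16, edgeR adjusted p = 0.0011) and its neighbour Hspa1b, with which it shares most of its sequence, from 103 to 546 CPM (2.40 ± 0.24, edgeR adjusted p = 0.0172). Klf2 rose by 2.04 ± 0.19, Lepr, the leptin receptor gene, by 1.42 ± 0.15, and Jun, a part of the AP-1 factor, by 1.11 ± 0.12 (SE, n = 2 per group). In aPD1 the 3 genes that rose were Hspa1b (2.45 ± 0.24), Hspa1a (2.25 ± 0.16) and Zfand2a, a gene induced by protein damage (1.07 ± 0.11, edgeR adjusted p = 0.029). In the libraries titled aTREM2-aPD1, which the annotation names the TREM2 antibody alone, no gene passed against CTRL by edgeR, 2499 had an unadjusted p below 0.05, and DESeq2 called 172. The log2 fold change of Trem2 against CTRL was 0.05 ± 0.11 in each of the 3 arms, none of which passed. Because reads of Hspa1a and Hspa1b can be assigned to either gene, their separate levels are uncertain.

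The dissociation stress list rose in macrophages of aPD1 (median 0.59, camera adjusted p = 1.5e-40) and held with an estimated correlation (adjusted p = 0.0462). In the libraries titled aTREM2 it had 4 of 14 members risen, 10 when adjusted over the list alone, and a median of 0.84 (camera adjusted p = 6.7e-34, adjusted p = 0.054 with an estimated correlation). In the same libraries the inflammatory cytokine list (median 0.63, camera adjusted p = 1.0e-07) and costimulation list (median 0.32, camera adjusted p = 0.00503) lay higher, both at an adjusted p = 0.354 with an estimated correlation. In the libraries titled aTREM2-aPD1 the interferon gamma response lay lower (median −0.38, camera adjusted p = 0.000219) and proliferation higher (median 0.68, camera adjusted p = 2.3e-05), both at an adjusted p = 0.537 with an estimated correlation. MHC class I lay lower there (median −0.18, camera adjusted p = 0.0295, adjusted p = 0.658 with an estimated correlation). In aPD1 the monocyte list lay lower (median −0.28, camera adjusted p = 0.0219, adjusted p = 0.427 with an estimated correlation). T cell markers lay lower in macrophages of the libraries titled aTREM2 (median −1.15), aPD1 (−1.24) and titled aTREM2-aPD1 (−0.89), with camera adjusted p = 3.6e-10, 8.2e-16 and 7.3e-07, and adjusted p = 0.233, 0.35 and 0.359 with an estimated correlation.

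Under the annotation's names, macrophages with the TREM2 antibody alone had 0 genes called against CTRL and the combination had 15. For the libraries titled aTREM2, the count of 15 was 1 without CTRL 2, 32 without CTRL 1, 28 without aTREM2 1, 4 without aTREM2 2 or either aTREM2-aPD1 library, and 5 without either aPD1 library. For aPD1, the count of 3 was 0 without aPD1 1, 1 without aPD1 2, and 5 without aTREM2 1 or aTREM2 2. For the libraries titled aTREM2-aPD1, the count of 0 was 10 without aTREM2 1, 3 without aTREM2 2 and 6 without CTRL 1.

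**Figure D4:**
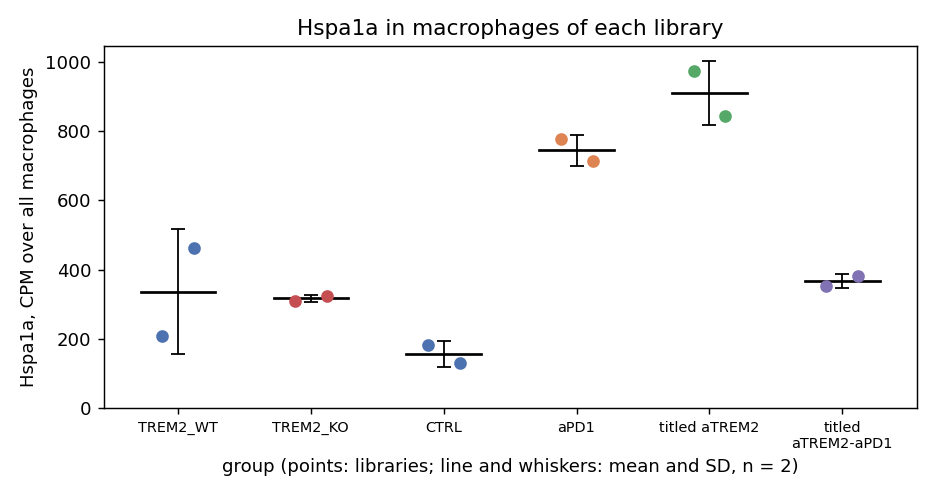
Hspa1a in macrophages of each library, in CPM (vertical axis), by group (horizontal axis), with points for libraries and a line with whiskers for the mean and SD of n = 2. The 4 libraries of aPD1 and titled aTREM2 lie between 713 and 974 CPM, and the other antibody libraries between 131 and 382 CPM.

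Adding the TREM2 antibody to PD-1 blockade was read from the libraries titled aTREM2-aPD1 against aPD1. In macrophages Fchsd2 (−1.04 ± 0.11), Zfand2a (−0.99 ± 0.11) and Rgl1, a regulator of Ral GTPases (−0.82 ± 0.09), fell, each at edgeR adjusted p = 0.0256 (SE, n = 2 per group), among 2 genes that rose and 5 that fell. The interferon gamma response lay lower (camera adjusted p = 9.3e-05, adjusted p = 0.617 with an estimated correlation). Cluster 5 rose to 10.4% from 0.149% of macrophages (edgeR adjusted p = 0.00536) and cluster 4 fell to 1.62% from 15.6% (edgeR adjusted p = 0.00263). Under the annotation's names the combination stood at 7.84% for cluster 5 and 6.14% for cluster 4, and its difference from aPD1 was not tested. With the labels exchanged the count of 7 was 3. It was 0 without aPD1 1, aPD1 2 or aTREM2-aPD1 1, 1 without aTREM2-aPD1 2, 128 without aTREM2 1, 124 without aTREM2 2, 42 without CTRL 1 and 20 without CTRL 2.

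The interaction asked whether the TREM2 antibody acts differently with and without PD-1 blockade. In macrophages 16 genes had a lower and 1 a higher interaction. Hspa1b (−4.01 ± 0.33), Hspa1a (−3.58 ± 0.22), Klf2 (−2.47 ± 0.27), Hsph1, another chaperone gene (−1.99 ± 0.20), and Lepr (−1.90 ± 0.22) led, with edgeR adjusted p between 0.00121 (Hspa1a) and 0.0157 (Klf2). The others included Dnajb1, Zfand2a, Gadd45b, Klf6 and Rhob. The dissociation stress list fell, with all 14 members negative, 3 fallen over all genes, 13 adjusted over the list alone, and a median of −1.17 (camera adjusted p = 4e-44, adjusted p = 0.0378 with an estimated correlation). Under the annotation's names these 17 genes are the effect of the PD-1 antibody over all 8 libraries, with 16 higher and 1 lower, and no gene passes the interaction by edgeR (710 at an unadjusted p below 0.05). The count of 17 was 4 without aPD1 1 or aTREM2-aPD1 2, 9 without aPD1 2, 6 without aTREM2-aPD1 1, 7 without CTRL 2, 29 without CTRL 1 and 77 without aTREM2 2.

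Among T/NK cells, 8 genes rose against CTRL in the libraries titled aTREM2, among them Klf2 (1.09 ± 0.13), Jun (0.79 ± 0.13), Dpm1 (0.77 ± 0.12) and Hsp90aa1 (0.75 ± 0.13; SE, n = 2 per group, edgeR adjusted p between 0.00488 and 0.0391). In aPD1 4 genes rose and 16 fell. The falls were led by Il2ra, the interleukin 2 receptor chain of activated and regulatory T cells (−1.43 ± 0.15, 73.9 to 27.6 CPM, edgeR adjusted p = 0.000198), the T cell receptor constant gene Trac (−1.32 ± 0.15), the costimulatory receptor gene Icos (−1.22 ± 0.16), Ikzf2 (−1.09 ± 0.11) and Rora (−1.03 ± 0.16), and Polr2l rose by 0.83 ± 0.12. T cell markers fell as a set (median −0.96, camera adjusted p = 8.2e-35, adjusted p = 0.0193 with an estimated correlation). T-cell-like cells made up 14.4% and 12% of the T/NK cells in aPD1 and 21.9% and 27.0% in CTRL. Il2ra and Ikzf2 stood at 0.16 and 0.04 in NK-like cells alone. By edgeR, NK-like cells alone gave 1 call and T-cell-like cells alone 1. The regulatory T cell list had 2 of 9 members fallen, 7 adjusted over the list alone, and a median of −1.43 (camera adjusted p = 6.1e-23, adjusted p = 0.169 with an estimated correlation), and the naive and memory list lay lower (camera adjusted p = 0.00138, adjusted p = 0.401 with an estimated correlation).

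Against CTRL, 16 genes rose and 13 fell in T/NK cells of the libraries titled aTREM2-aPD1. Stmn1 rose by 1.41 ± 0.15 (edgeR adjusted p = 0.000856), Cd68 by 1.11 ± 0.17, Klf2 by 0.94 ± 0.13, Rexo2 by 0.72 ± 0.14 and Nfkbia by 0.58 ± 0.10. Gtf3c2 (−0.91 ± 0.17), Itgb3 (−0.90 ± 0.14), Lars2 (−0.84 ± 0.12), Uhmk1 (−0.81 ± 0.15) and Itga1 (−0.72 ± 0.11) fell. Proliferation genes lay higher, with 15 of 15 positive, Stmn1 risen, 10 risen when adjusted over the list alone, and a median of 0.77 (camera adjusted p = 1.2e-11, adjusted p = 0.0583 with an estimated correlation). Against aPD1, 124 genes rose and 53 fell. The T cell transcription factor gene Bcl11b rose by 1.95 ± 0.26, Ifi27l2a by 1.94 ± 0.26, Trac by 1.54 ± 0.15 and Rora by 1.53 ± 0.17, together with the macrophage genes Lyz2 (1.92 ± 0.22) and Trem2 (1.24 ± 0.28, 8.71 to 21 CPM, edgeR adjusted p = 0.0401). T-cell-like cells made up 29.0% and 37.9% of the T/NK cells there and 14.4% and 12% in aPD1, and by edgeR T-cell-like cells alone gave 21 calls, of which 10 were among the 177, and NK-like cells alone 30, of which 17 were. Atp8b2 (−1.04 ± 0.21), Nod1 (−0.97 ± 0.22), Itgb3 (−0.87 ± 0.15), Arap3 (−0.85 ± 0.18) and Lars2 (−0.83 ± 0.12) fell. The regulatory T cell list had 4 of 9 members risen, 8 adjusted over the list alone (camera adjusted p = 3.7e-24, adjusted p = 0.0727 with an estimated correlation), and extracellular matrix remodelling lay higher (median 1.04, camera adjusted p = 3.9e-05, adjusted p = 0.261 with an estimated correlation).

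In the T/NK interaction 23 genes were higher and 3 lower, led by Il2ra (2.25 ± 0.21, edgeR adjusted p = 0.000195), Trac (1.77 ± 0.21), Ikzf2 (1.53 ± 0.16), Odc1, the first enzyme of polyamine synthesis (1.13 ± 0.18), and Camk4 (1.13 ± 0.21), against Hsph1 (−0.99 ± 0.19) and Vcpkmt (−0.94 ± 0.18). Mitochondrial transcripts lay higher (median 0.17, camera adjusted p = 0.0492, adjusted p = 0.592 with an estimated correlation). T cell markers rose as a set (median 1.21, camera adjusted p = 2.5e-26, adjusted p = 0.0342 with an estimated correlation). Trac and Ikzf2 stood at −0.06 and −0.07 in NK-like cells alone, and T-cell-like cells alone gave 0 edgeR calls, with 424 genes at an unadjusted p below 0.05. Under the annotation's names no gene passes the interaction by edgeR (631 at an unadjusted p below 0.05), and the PD-1 antibody over all 8 libraries has 3 genes higher and 23 lower. With the labels exchanged, the comparison of aTREM2 with CTRL had 29 genes in place of 8. The comparison of aTREM2-aPD1 then had 8 genes in place of 29 against CTRL and 7 in place of 177 against aPD1.

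Leaving out libraries moved these T/NK counts. For the libraries titled aTREM2 the 8 became 118 without CTRL 2, 78 without aTREM2 1, 21 without CTRL 1, 2 without aPD1 2, and 1 without aTREM2-aPD1 1 or aTREM2-aPD1 2. For aPD1 the 20 became 52 without CTRL 1, 47 without CTRL 2 and 44 without aPD1 1. For the libraries titled aTREM2-aPD1 the 29 became 1395 without CTRL 2, 9 without CTRL 1, 179 without aTREM2 1, 177 without aTREM2 2, 17 without either aPD1 library, 3 without aTREM2-aPD1 1 and 2 without aTREM2-aPD1 2. Against aPD1 the 177 became 29 without aTREM2-aPD1 2, 84 without aTREM2-aPD1 1, 71 without aPD1 1, 67 without aPD1 2, 335 without aTREM2 1, 330 without aTREM2 2, 406 without CTRL 1 and 388 without CTRL 2. The interaction's 26 became 12 without aTREM2-aPD1 2, 95 without aTREM2 2, 109 without CTRL 1 and 43 without CTRL 2.

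The arms differed from CTRL in a few shares of cells. In the libraries titled aTREM2, T-cell-like cells made up 2.93% against 7.60% in CTRL (log2 −1.38 ± 0.39, edgeR adjusted p = 0.0319), neutrophil-like cells 3.75% against 1.64% (log2 1.19 ± 0.33, edgeR adjusted p = 0.0319), conventional dendritic-like cells 1.76% against 3.28% (edgeR adjusted p = 0.0381) and unnamed proliferating cells 0.849% against 2.84% (edgeR adjusted p = 0.0319). In those titled aTREM2-aPD1, macrophage cluster 4 made up 1.62% of macrophages against 7.91% in CTRL (log2 −2.28 ± 0.49, edgeR adjusted p = 0.0176). The interaction passed for macrophage clusters 4 (−2.89 ± 0.67, edgeR adjusted p = 0.027) and 7 (2.13 ± 0.62, edgeR adjusted p = 0.0428). Under the annotation's names the shares of the libraries titled aTREM2 belong to the combination and those of the libraries titled aTREM2-aPD1 to the TREM2 antibody alone. The interaction of clusters 4 and 7 is then an effect of the PD-1 antibody of opposite sign.

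Loss of the receptor and the antibody against it were compared across macrophage genes, since both act on TREM2 and the experiments share no library. Across 5203 genes above 20 CPM, the log2 fold changes of TREM2_KO over TREM2_WT and of the TREM2 antibody over none had Pearson's r = −0.520 and Spearman's rho = −0.593, and 26.8% of genes had the same direction. Without CTRL 1, Pearson's r was −0.341. Genes are not independent replicates, so no p-value is given. Spp1 (−2.22 in TREM2_KO and 1.46 with the antibody), Eno1 (−0.64 and 0.40), C5ar1 (−0.35 and 0.54), Egr1 (0.78 and −0.46) and Gm42418 (0.47 and −0.51) lay on opposite sides, whereas Cxcl9 (1.02 and 0.06) and Cd83 (0.84 and 0.04) had the same sign. At an unadjusted p below 0.05, 17 genes were higher in both, where independent lists give 212, and 8 were lower in both, where they give 136.

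**Figure D5:**
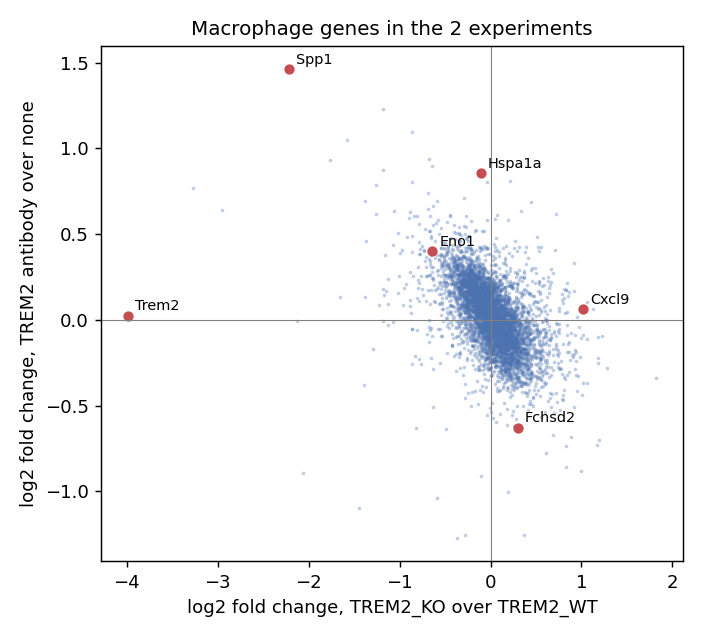
Log2 fold changes of macrophage genes for TREM2_KO over TREM2_WT (horizontal axis) and for the TREM2 antibody over none (vertical axis), with a point for each of 5203 genes. The cloud slopes downward, with r = −0.520.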

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

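The comparison of heat shock genes across cell classes and the test of free macrophage RNA were chosen after the results were seen. So were the analysis of single lymphoid classes and the removal of droplets rich in macrophage markers. The splits with 1 library of each group on either side were added then too. The other tests of this part were set before they were run. Those on the interaction genes and on the opposite fold changes still concern patterns already seen in the results. The effect of the TREM2 antibody differed between libraries with and without PD-1 blockade, by the interaction test of edgeR, for 17 genes in macrophages and 26 genes in T/NK cells. In macrophages the named genes were Hspa1b (−4.01), Hspa1a (−3.58), Klf2 (−2.47), Hsph1 (−1.99) and Lepr (−1.90), on the log2 scale. In T/NK cells they were Il2ra (2.25), Trac (1.77), Ikzf2 (1.53), Odc1 (1.13), Camk4 (1.13), Hsph1 (−0.99) and Vcpkmt (−0.94).

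Heat shock genes in macrophages set the aPD1 and titled aTREM2 libraries apart from the CTRL and titled aTREM2-aPD1 libraries. A different mix of macrophage clusters is argued against, since the median interaction of the 17 genes, in the called direction, was 1.56 with equal cluster weights, and Hspa1a separated these libraries in all 5 clusters tested. Exchanged labels, as the deposited annotation has them, leave 0 interaction genes by edgeR (710 at an unadjusted p below 0.05), and the 17 genes become an effect of the PD-1 antibody, which the titles do not give. Handling of whole libraries stays open, because it would hit the same 4 libraries. The 17 genes, of which only some are heat shock genes, were chosen by their effect in macrophages, where their median was 1.80. It was 0.70 (median absolute deviation 0.79) in NK-like cells, 1.16 in T-cell-like, 1.48 in neutrophil-like and 0.99 in conventional dendritic-like cells. An effect of PD-1 blockade on stress genes is therefore a candidate explanation that cannot be told apart from handling here.

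Macrophage-enriched genes that rose in T/NK cells of TREM2_KO may come from macrophages in the same droplets. The 53 such genes outside the marker list had a median log2 fold change of 1.11 (median absolute deviation 0.47), which was 0.78 (0.45) without T/NK droplets rich in macrophage markers, and 12 of them were still called. Over the same removal the 46 other risen genes went from 0.72 to 0.76 with 36 still called, and the 4 risen genes of the macrophage marker list, by which the droplets were chosen, from 0.78 to 0.16 with 1 still called. A larger amount of free macrophage RNA spread evenly over droplets is argued against. The median share of macrophage transcripts per T/NK cell was 1.15 times as high in TREM2_KO, while its 90th percentile was 2.08 times as high. That share is of 74 genes chosen for their high level in macrophages, rather than of the 53 risen genes. Free RNA whose make-up differs between the genotypes is not covered by it and stays open. Droplets that hold both cells stay open, as does a change of the lymphocytes by the genotype, which was not tested.

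The macrophage fold changes of TREM2_KO and of the TREM2 antibody ran in opposite directions (r = −0.520). Log transcript length correlated at 0.258 with the fold change of TREM2_KO and at −0.444 with that of the antibody, so a part through length stays open. Transcript length and GC content are argued against as the whole cause, with a partial correlation of −0.472 given both. A shift of whole libraries stays open, since the correlation was −0.319 in NK-like cells and −0.244 in T-cell-like cells. Differences between replicates stay open, since a partial correlation of −0.353 was left after those of the 6 groups were taken out, but single replicate differences are noisy, and 2 of the 8 splits with 1 library of each group on either side correlated as strongly as the real split (up to 0.738 in size). Chance is not excluded, because 11 of the 35 splits of the 8 antibody libraries into 4 and 4 gave a correlation as large in size, the highest of the other splits being 0.738, and a biological opposition of gene loss and antibody is not separated from these.

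For the number of genes called between 2 groups of 4, chance is not excluded either, since 2 of 35 splits gave as many in macrophages (17, highest other split 190) and in T/NK cells (23, highest other split 143). The highest other split was the same in both, with aPD1 1, aPD1 2, aTREM2 1 and CTRL 1 against the rest. This split is the real one with aTREM2 1 and CTRL 2 exchanged, so it keeps part of the antibody contrast. It therefore cannot show a structure of the samples apart from the antibody. The 8 splits with 1 library of each group on either side hold no antibody contrast. Each called 0 genes in macrophages and in T/NK cells, but differences between groups add to the spread within their sides. Their correlation with the fold change of TREM2_KO reached 0.738 in size. That of the split with aPD1 1, aPD1 2, aTREM2 1 and CTRL 1 against the rest was 0.734. Gm42418, a transcript that overlaps ribosomal RNA and was chosen after its values were seen, stood at 19939, 20922, 15218 and 17852 CPM in macrophages of the 4 libraries on the aPD1 side of this split. In the others it stood at 10645 (aTREM2 2), 10764 and 11190 (aTREM2-aPD1) and 14151 (CTRL 2), against 26027 and 25664 in TREM2_KO and 16940 and 20065 in TREM2_WT.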

How the results depend on the processing

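Cells of 5000 to 40000 UMIs, NK-like or T-cell-like cells alone and T/NK cells without droplets rich in macrophage markers were chosen after the data were seen. The sizes of the counts depend on the test, the filter and single libraries, and the cause of each move was not tested except where stated. A fit with 2 libraries per group leaves 2 residual degrees of freedom in the genotype experiment. The filter of 2000 UMIs removes 3 cells, and the deposited lymphoid table holds the same T/NK cells, so these settings test nothing. The labels tie no replicate number to a shared animal or day, so a batch shared by same-numbered libraries is neither given nor excluded. Differences between same-numbered replicates correlated at 0.00326 between TREM2_KO and TREM2_WT and between −0.179 and 0.397 among the antibody groups in macrophages, and at 0.119 and between 0.0209 and 0.231 in T/NK cells.

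Among the 14 gene comparisons, the counts in macrophages by DESeq2 were 1386 for TREM2_KO against TREM2_WT (4 by edgeR), 566 for the TREM2 antibody (17), 223 for aTREM2 against CTRL (15), 32 for aPD1 against CTRL (3), 172 for aTREM2-aPD1 against CTRL (0), 403 for aTREM2-aPD1 against aPD1 (7) and 195 for the interaction (17). In the same order, no filter on low counts gave 475, 1800, 917, 282, 1261, 1480 and 813 genes, and a replicate block gave 0, 24, 37, 5, 3, 35 and 43. In T/NK cells DESeq2 gave 68 for TREM2_KO against TREM2_WT (190 by edgeR), 177 for the TREM2 antibody (109), 30 for aTREM2 against CTRL (8), 60 for aTREM2-aPD1 against CTRL (29) and 42 for the interaction (26). Without the filter the 7 T/NK counts were 426, 647, 118, 165, 711, 693 and 252, and with a replicate block they were 344, 334, 27, 36, 342, 361 and 37. Cells of 5000 to 40000 UMIs gave 9 genes for TREM2_KO against TREM2_WT in macrophages, and 2 groups of 4 libraries gave 23 for the TREM2 antibody in T/NK cells.

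Exchanged labels gave 0, 15, 3 and 0 genes in macrophages for aTREM2 against CTRL, aTREM2-aPD1 against CTRL, aTREM2-aPD1 against aPD1 and the interaction, and 29, 8, 7 and 0 in T/NK cells. At an unadjusted p below 0.05 the interactions then had 710 and 631 genes by edgeR. NK-like cells alone gave 15 genes for the TREM2 antibody, 2 for aTREM2 and 1 for aPD1 against CTRL, 30 for aTREM2-aPD1 against aPD1 and 11 for the interaction. T-cell-like cells alone gave 38 for TREM2_KO against TREM2_WT and 93 for the TREM2 antibody. Against CTRL they gave 21 for aTREM2, 1 for aPD1 and 16 for aTREM2-aPD1. They gave 21 for aTREM2-aPD1 against aPD1 and 0 for the interaction (424 at an unadjusted p below 0.05 by edgeR). Fewer cells enter these sums. Without droplets rich in macrophage markers the T/NK counts were 104 for TREM2_KO against TREM2_WT and 14 for aTREM2 against CTRL.

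Leaving out a library gave, in macrophages, 0 (without TREM2_KO 1 or 2) to 7550 (without TREM2_WT 2) genes for TREM2_KO against TREM2_WT, 0 (aPD1 1 or 2) to 549 (aTREM2 1) for the TREM2 antibody, 1 (CTRL 2) to 32 (CTRL 1) for aTREM2 against CTRL, 0 (aPD1 1) to 5 (aTREM2 1 or 2) for aPD1 against CTRL, 0 to 10 (aTREM2 1) for aTREM2-aPD1 against CTRL, 0 to 128 (aTREM2 1) for aTREM2-aPD1 against aPD1 and 4 (aPD1 1 or aTREM2-aPD1 2) to 77 (aTREM2 2) for the interaction. In T/NK cells the ranges were 92 (TREM2_KO 1) to 736 (TREM2_WT 2), 19 (aTREM2-aPD1 2) to 1047 (CTRL 2), 1 (aTREM2-aPD1 1 or 2) to 118 (CTRL 2), 21 (aPD1 2) to 52 (CTRL 1), 2 (aTREM2-aPD1 2) to 1395 (CTRL 2), 29 (aTREM2-aPD1 2) to 406 (CTRL 1) and 12 (aTREM2-aPD1 2) to 109 (CTRL 1). The correlation of fold changes lay between −0.649 (CTRL 2) and −0.341 (CTRL 1), and it was −0.516 at a minimum of 50 CPM. The log2 fold change of Trem2 in macrophages lay between −4.14 (TREM2_WT 2) and −3.81 (TREM2_WT 1). Its call was lost at −4.00 without TREM2_KO 1, −3.96 without TREM2_KO 2 and −3.98 with a replicate block.

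Of 280 list tests, 118 were called by camera at the preset correlation, 2 with an estimated correlation and 8 by fry. Class shares of TREM2_KO against TREM2_WT had 0 calls by edgeR, 3 with cells of 5000 to 40000 UMIs, 3 without neutrophil-like cells in the denominator, and 0 to 4 (TREM2_WT 2) with a library left out. Macrophage clusters of that comparison had 6 calls, 3 with a block, and 0 (TREM2_KO 1 or 2) to 8 (TREM2_WT 1 or 2) with a library left out. Class shares with the TREM2 antibody had 1 call, 3 with cells of 5000 to 40000 UMIs, 0 without neutrophil-like cells in the denominator, where that class is absent, 2 with a block, and 0 to 5 (aTREM2 1) with a library left out. Macrophage clusters with the TREM2 antibody had 2 calls, and 2 to 4 (aTREM2 1) with a library left out.

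Some directions turned. For TREM2_KO against TREM2_WT, H2-DMb1 stood at −0.11 and Atf3 at −0.30 in NK-like cells, and P2ry14 at 0.49 and Fasl at 0.36 in T-cell-like cells. For the TREM2 antibody, Cd3e (−0.25), Uhrf2 (−0.030), Igtp (−0.016) and Ikzf2 (−0.39) turned in NK-like cells, Xcl1 (−0.11) in T-cell-like cells and Trem2 (−0.22) without droplets rich in macrophage markers. In NK-like cells Il2ra (0.16) and Ikzf2 (0.044) turned for aPD1 against CTRL, and Trac (−0.063) and Ikzf2 (−0.074) for the interaction. With labels exchanged, Trem2 in T/NK cells stood at 0.97 for aTREM2 and −0.54 for aTREM2-aPD1 against CTRL, −0.26 for aTREM2-aPD1 against aPD1 and −1.22 for the interaction, where Hsph1 stood at 0.28. Trem2 stood at −0.058 for aTREM2-aPD1 against CTRL without droplets rich in macrophage markers. With a library left out, the log2 fold change of macrophage cluster 2 lay between −0.51 (TREM2_WT 1) and 0.66 (TREM2_WT 2), that of fibroblast- or sarcoma-like cells with the TREM2 antibody between −1.74 (aTREM2 2) and 1.54 (aPD1 1), and that of plasmacytoid dendritic-like cells between −0.74 (aTREM2 2) and 0.56 (CTRL 1).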

Other observations

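Genes that mark the sex of the animal split the experiments. In macrophages of the 4 genotype libraries Ddx3y, a gene on chromosome Y, stood between 48.8 and 72.8 CPM, and Xist, the RNA that silences an X chromosome in females, at no more than 0.842 CPM. In macrophages of the 8 antibody libraries Xist stood between 679 and 790 CPM and Ddx3y had 0 UMIs. In the fibroblast- or sarcoma-like cells of the genotype libraries, which the CD45 sort would mostly remove, Xist stood between 420 and 640 CPM and Ddx3y between 4.60 and 11.4 CPM. The epithelial genes Krt8, Krt18 and Epcam had 0 CPM in those cells, and Col3a1, a fibrillar collagen gene, stood between 1759 and 4734 CPM.

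Gm47283 fell in TREM2_KO against TREM2_WT outside macrophages too, by 1.67 ± 0.14 in NK-like cells (log2 fold change with SE, n = 2 per group, edgeR adjusted p = 1.7e-11) and by 1.53 ± 0.24 in T-cell-like cells (edgeR adjusted p = 0.0227). In the antibody libraries, which had no Ddx3y UMIs in these cells either, it stood between 135 and 244 CPM in NK-like and between 80.5 and 211 CPM in T-cell-like cells. The log2 ratios of its mean CPM, which were not tested, were −1.62 in neutrophil-like, −1.66 in conventional dendritic-like and −0.08 in fibroblast- or sarcoma-like cells. In macrophages Eif2s3y stood at −0.46 ± 0.08 and Ddx3y at 0.45 ± 0.07 (edgeR adjusted p = 0.0779 and 0.0749). Hemoglobin transcripts made up 0.0142% of UMIs in aTREM2-aPD1 2, 0.00585% in TREM2_KO 1 and 0.00114% in CTRL 2, and less in each of the other 9 libraries.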
